A study of Arabidopsis thaliana with 8 samples.

How the data were processed

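Small RNA was measured in 8 libraries from seedlings of Arabidopsis thaliana Columbia-0 and the ago1-57 mutant, 2 replicates each of total RNA and of RNA bound to AGO1 in both genotypes. Per the labels' protocols, seedlings grew for 2 weeks on agar medium at 22 °C by day and 20 °C by night with 16 h of light, RNA was extracted with TRI-reagent, AGO1 was immunoprecipitated from 300 mg of tissue, and libraries made by an adapted Illumina protocol were sequenced on an Illumina HiSeq. The deposited files hold, per library, each distinct read sequence of 18 to 35 nt with its raw count as the authors made it, with no normalization, and 13106308 distinct sequences over all libraries. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 and the TAIR10 genome. Adapter trimming and read filters are not given in the sources used here. Groups were taken from the sample titles. A source field follows the genotype instead, calling wild-type IP libraries total RNA and mutant total RNA libraries immunoprecipitated RNA, and the share of reads beginning with U, 83.3% to 90.7% in libraries titled as IP and 21.1% to 31.6% in the others, was checked beside the titles. The mutant's genotype field gives another allele name than the titles, and the titles' name ago1-57 is used. The design text describes the replicates as biological, and nothing says that equal replicate numbers share a batch.

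Reads were matched to the TAIR10.1 assembly (RefSeq) without mismatch. A mature miRNA count sums genome-matched reads of 19 to 24 nt whose ends lie within 2 nt of both ends of an annotated mature sequence, and identical mature sequences are 1 feature, which made 350 features from 428 annotated entries. Reads that could belong to more than 1 feature made up 0.555% of mature reads. Locus counts are reads of 21 to 22 nt with 1 exact genome match on either strand within a gene, without MIR, structural RNA and organellar genes, over 36575 genes of which 27664 had a read. Strand was not used, so reads of overlapping or antisense genes cannot be told apart, and near-identical paralogs lose shared reads. The RefSeq annotation lacks many transposon genes, so reads called intergenic can come from them. Ribosomal RNA reads were recognised with the annotated genes extended by 4000 bp. miRNA duplexes join both annotated arms, 92 loci that became 73 after loci sharing an arm sequence were merged, of which 55 were tested. Counts of a merged duplex are summed per arm, so it can hold arms of unlike sequence. siRNA duplexes are pairs of 21-nt sequences with 1 genome match that leave 2-nt overhangs and have at least 50 reads over all libraries, 1268 in all. Unpaired nucleotides and energies came from RNAduplex 2.7.2.

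Tests used edgeR 4.0.16 (glmQLFit and glmQLFTest, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3 on all 8 libraries with 4 group means, which share 1 estimate of spread. Genotype and interaction tests of miRNAs and loci used TMM scaling and filterByExpr, enrichment of IP over total RNA used all genome-matched reads as library size, and the 72 classes of length and first nucleotide used all reads. Duplexes were tested on 16 columns (library by strand) with a library term and a strand by group term, so that library totals cancel. The guide was the strand of higher mean abundance over all 8 libraries, and the guide by family keeps this rule for families without a listed convention. Lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01 and with an estimated one: 9 lists by function and 2 by rule (first nucleotide, length of 22 nt), 11 in all, and 4 lists of loci. Shares of strands at a locus use summed counts, the locus test has at least 5 duplexes, and a pseudocount of 0.5 reads entered the ratios compared with pairing, whose p-values are from 100000 permutations, two-sided. Counting, matching and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. Groups, tests, lists and the rule for named genes were fixed before the data were examined, while the guide by family, by 5′ U or by the wild-type libraries, the summary by locus and the duplex interaction were chosen after the data were seen.

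Named miRNAs are, per genotype comparison, up to 12 with the largest change past the threshold, at least 50 RPM in a group and no overlap between libraries of the groups, the 8 most abundant in wild-type IP and 2 to 4 of highest abundance per list. Named loci are the TAS loci, up to 10 with the largest change at an average of at least 20 reads and no overlap between libraries, AGO1, AGO2, DCL1 and the fixed lists. Named duplexes are up to 10 of each kind with the largest change. Exceptions, chosen after their values were seen, are miR162a-3p, miR168a-3p, miR173-3p, miR863-5p, miR5651, miR852, miR869.2 and miR825 where they stand for a list or test, the duplexes MIR167a, MIR168a and MIR390a, the gene MEE40, and the genes of the closing observations.

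The depth of 13648745 to 50598709 reads per library puts 3 reads at 0.0662 to 0.277 RPM. Reads carry no molecular identifiers, so floors cover counting error only. Counts were simulated with 1 mean per feature over all 8 libraries, or 1 passenger share for duplexes, and 1 spread for all groups. The rates need not hold where IP and total RNA differ in level or spread. In these counts the miRNA test recovered 18.2%, 63.6% and 83.3% of features changed by log2 1, 2 and 3 in IP, with 4% false calls. In total RNA it recovered 0%, 50% and 80% with edgeR alone. The locus test recovered 0%, 20% and 52.5% in IP, with 8% false calls, and 0%, 16.1% and 43.3% in total RNA. miRNA duplexes were recovered at 20% for log2 3 and 85.7% for log2 5 in IP, with 11.1% false calls, and at 40% for log2 3 in total RNA. These rates rest on 5 and 7 changed duplexes in IP and 5 in total RNA. siRNA duplexes were recovered at 4.35%, 10.3% and 25% for log2 3, 5 and 8 in IP and at 2.56% for log2 8 in total RNA, so most changed siRNA duplexes would be missed. Size classes were recovered at 75% and 100% for log2 2 and 3 in IP.

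Alternatives were DESeq2 1.42.0, library total or TMM scaling, no filter on low counts, a replicate block, the 4 libraries compared alone, exact mature sequences, weighted multi-mapping reads, at least 200 reads per duplex, other guide rules, guide positions 2 to 13 for pairing, genome-matched reads for size classes, and each library left out in turn, where the lone library of a group is assumed to vary like the others. Added after the data were seen were the guide rules named above, further pairing measures, miRNA counts with 3′ tailed reads, and the alternatives for the duplex interaction and the siRNA loci.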

Results

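Small RNAs of 18 to 35 nt were sequenced from 2-week-old Arabidopsis thaliana seedlings of the wild type Columbia-0 and of the ago1-57 mutant, which carries an altered allele of AGO1, the main effector protein of plant microRNAs (miRNAs). Total RNA and RNA recovered by AGO1 immunoprecipitation (IP) were sequenced from both genotypes, which gave 4 groups of 2 biological replicates. The comparisons ask which small RNAs differ in the mutant, in total RNA and in AGO1, and whether mutant AGO1 holds more of the passenger strand, the strand of a small RNA duplex that is normally discarded. The wild-type libraries of total RNA held 50598709 and 38502326 reads and those of ago1-57 held 45305077 and 36383826. The wild-type IP libraries held 17205743 and 34127974 reads and those of ago1-57 held 26123436 and 13648745. Exact genome matches made up 89.4% to 90.7% of reads in total RNA, 85.4% and 91.5% in wild-type IP, and 78% and 79.3% in ago1-57 IP. Libraries titled as IP began with U in 83.3% to 90.7% of reads, against 21.1% to 31.6% in those titled as total RNA. A second label field names the material by genotype instead, so the groups follow the titles. Small RNA reads do not show the AGO1 protein or its messenger RNA, so the genotype itself was not checked. Levels are in RPM, reads scaled to a common total of genome-matched reads, as mean ± SD of n = 2 libraries. Changes are log2 values ± SE of ago1-57 over the wild type unless stated. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A level of 3 reads, taken as the floor of each library, equals 0.0662 to 0.277 RPM and covers counting error only. Coordinates refer to the TAIR10.1 assembly with its RefSeq annotation.

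The size class of most miRNAs took a smaller share of total RNA in ago1-57. Reads of 21 nt made up 18.1% and 18.9% of the wild-type libraries of total RNA and 8.31% and 4.94% of the mutant ones. Reads of 24 nt, mostly siRNAs of the DNA methylation pathway, made up 20.5% and 23.2% in the wild type and 22.5% and 25.9% in the mutant. Mature miRNAs summed to 149949 and 148682 RPM in wild-type total RNA and to 46706 and 24810 RPM in ago1-57. Without miR165 and miR166, which regulate leaf polarity genes, the sums were 50057 and 49634 RPM in the wild type and 31491 and 19940 RPM in the mutant. In the IP, mature miRNAs summed to 625481 and 784455 RPM in the wild type and to 680461 and 558695 RPM in ago1-57. The sums were not tested. Among 72 classes of length and first nucleotide, 1 passed in total RNA: 20-nt reads beginning with U, the class of miR156 and miR158, fell from 1.84% ± 0.0965 to 0.375% ± 0.246 of reads (log2 change -2.30 ± 0.51, adjusted p = 0.00634). The 20-nt classes beginning with A, C and G had log2 changes of -1.72, -1.79 and -1.44, and the 19-nt classes -1.50 to -2.05. Classes of 33 to 35 nt were at 0.75 to 1.41. None of these passed, and a fall limited to reads beginning with U or to miRNAs is not shown. The 21-nt class beginning with U went from 13.1% ± 0.188 to 3.34% ± 1.56 and did not pass (log2 change -1.97 ± 0.57, adjusted p = 0.0563). In the IP, 4 classes rose and 2 fell. The 24-nt class beginning with A, typical of AGO4, rose from 0.646% ± 0.119 to 2.48% ± 1.14 (log2 change 1.94 ± 0.47, adjusted p = 0.00933). The 24-nt, 22-nt and 33-nt classes beginning with G also rose, and the 26-nt and 27-nt classes beginning with C passed as lower. Both stood higher in WT_AGO1-IP replicate 2 (0.328% and 0.446%) than in replicate 1 (0.100% and 0.123%), and edgeR called 0 classes lower in IP without that replicate, either WT_total replicate, ago1-57_total replicate 2 or either ago1-57_AGO1-IP replicate. DESeq2 called 13 classes in total RNA and 15 in IP, and an unadjusted p under 0.05 was reached by 10 and 14 classes. The edgeR count in total RNA was 0 without WT_total replicate 1, ago1-57_total replicate 2 or either ago1-57_AGO1-IP replicate, and 2 without ago1-57_total replicate 1 or either WT_AGO1-IP replicate. The IP count was 15 without WT_AGO1-IP replicate 1, 3 without WT_total replicate 1 or 2 or ago1-57_total replicate 2, and 2 without WT_AGO1-IP replicate 2. It was 1 without ago1-57_AGO1-IP replicate 2, which ended the call of the 24-nt class beginning with A.

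**Figure D1:**
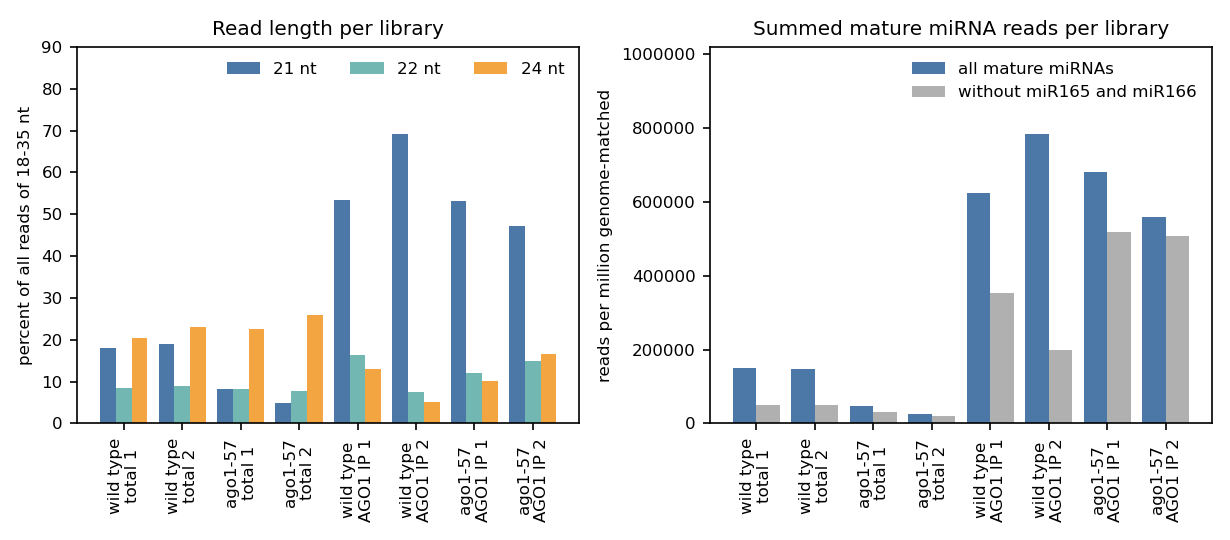
Share of 21-, 22- and 24-nt reads in percent of all reads (left) and summed mature miRNAs in RPM with and without miR165 and miR166 (right), with 1 group of bars for each of the 8 libraries. In total RNA the 21-nt share is 18.1% and 18.9% in the wild type and 8.31% and 4.94% in ago1-57.

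In total RNA of ago1-57, several strands usually regarded as passengers were higher and several abundant guide strands lower than in the wild type. The partner strand of miR162, miR162a-5p (chromosome 5, 2634998 to 2635019, minus strand), rose from 21.6 ± 0.0425 to 429 ± 32.6 RPM (log2 change 5.06 ± 0.57, adjusted p = 0.00132). Passenger strands of families that regulate auxin response factors, growth regulators and scarecrow-like factors rose too. miR160c-3p (chromosome 5, 19009095 to 19009115) went from 5.23 ± 1.9 to 79.1 ± 10.8 RPM. miR396a-3p (chromosome 2, 4142331 to 4142351) rose from 58.5 ± 16.0 to 357 ± 19.5 RPM and miR170-5p (chromosome 5, 26411635 to 26411655) from 20.3 ± 2.82 to 134 ± 44.2 RPM. The guide miR166a-3p, encoded by 7 loci (MIR166a at chromosome 2, 19176241 to 19176261), fell from 86857 ± 726 to 8425 ± 6478 RPM (log2 change -3.01 ± 0.77, adjusted p = 0.0324), while miR166a-5p rose from 93.1 ± 13.6 to 242 ± 75.2 RPM. miR396b-5p (chromosome 5, 13611808 to 13611828) fell from 3253 ± 152 to 518 ± 407 RPM. miR398b-3p (chromosome 5, 4691107 to 4691127), which targets copper superoxide dismutase transcripts, fell from 3081 ± 498 to 604 ± 393 RPM. miR156a-5p (chromosome 2, 10676534 to 10676553), which times the vegetative phase change, fell from 6518 ± 166 to 1417 ± 897 RPM (log2 change -1.77 ± 0.36, adjusted p = 0.0120). These levels leave out reads with 3′ tails unlike the locus. In total RNA such reads were 21.3% and 20.7% of miR156a-5p in the wild type and 43.8% and 64.9% in ago1-57. Part of its fall may thus be reads not counted. The young miRNA miR822-5p (chromosome 5, 897287 to 897307) fell from 51.5 ± 2.13 to 6.52 ± 3.63 RPM and miR396a-5p (chromosome 2, 4142443 to 4142463) from 278 ± 18.1 to 44.7 ± 27.1 RPM. miR158a-5p (chromosome 3, 3366391 to 3366411) rose from 17.8 ± 2.08 to 98.8 ± 54.9 RPM. Of 227 miRNAs tested, 14 rose and 14 fell. With library totals in place of TMM scaling 10 rose and 20 fell among 215 tested, and TMM had moved the median log2 change by 0.53. Library totals ended the calls of miR156a-5p and miR166a-5p, with log2 changes of -2.20 ± 0.82 and 1.38 ± 0.73. With exact mature sequences 26 rose and 3 fell, and the calls of miR156a-5p, miR160c-3p, miR166a-3p, miR396a-5p, miR396b-5p and miR398b-3p ended. Without WT_total replicate 1 or 2 edgeR called 0 miRNAs, against 68 at an unadjusted p under 0.05 and 45 by DESeq2 with all libraries. The count was 13 and 11 without ago1-57_total replicate 1 or 2, either of which ended the calls of miR156a-5p, miR166a-3p, miR166a-5p, miR396a-5p and miR398b-3p, and the latter that of miR396b-5p. Without ago1-57_AGO1-IP replicate 1 the calls of miR156a-5p, miR166a-3p and miR398b-3p ended, and without replicate 2 that of miR166a-5p. The count was 44 and 47 without WT_AGO1-IP replicate 1 or 2 and 83 with the 4 libraries of total RNA alone.

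In AGO1 IP of ago1-57, passenger strands of several families were higher and several guide strands lower than in the wild type. miR162a-5p rose from 12.8 ± 8.42 to 1637 ± 533 RPM (log2 change 6.21 ± 0.61, adjusted p = 0.000156). miR399c-5p (chromosome 5, 24962497 to 24962517), the passenger strand of a phosphate-starvation miRNA, rose from 0.178 ± 0.156 to 145 ± 75.0 RPM (log2 change 8.28 ± 0.98, adjusted p = 0.000430). miR158a-5p rose from 21.6 ± 13 to 1387 ± 79.6 RPM and miR166a-5p (chromosome 2, 19176128 to 19176148) from 4.17 ± 1.08 to 189 ± 26.0 RPM. miR170-5p rose from 55.7 ± 11.8 to 982 ± 113 RPM, miR171c-5p (chromosome 1, 22930157 to 22930177) from 11.8 ± 8.12 to 315 ± 127 RPM and miR167a-3p (chromosome 3, 8108172 to 8108192) from 6.22 ± 2.46 to 197 ± 59.4 RPM. Among guides, miR160a-5p (chromosome 2, 16340282 to 16340302) fell from 55.8 ± 31.1 to 3.09 ± 1.11 RPM (log2 change -5.42 ± 0.79, adjusted p = 0.00136). miR319a (chromosome 4, 12353109 to 12353129), a regulator of TCP transcription factors, fell from 1396 ± 965 to 210 ± 135 RPM, and miR396a-5p fell from 1294 ± 51.7 to 192 ± 41.0 RPM. miR822-5p fell from 292 ± 177 to 24.5 ± 1.73 RPM and miR5651 (chromosome 3, 17178489 to 17178509) from 493 ± 349 to 30.3 ± 10.5 RPM. miR390a-5p (chromosome 2, 16061971 to 16061991), the AGO7 cargo that triggers TAS3 siRNAs, fell from 412 ± 4.37 to 78.7 ± 18.2 RPM (log2 change -3.45 ± 0.46, adjusted p = 0.000746). Of the 8 most abundant miRNAs in wild-type IP, miR166a-3p fell from 366510 ± 163312 to 82931 ± 60153 RPM (log2 change -3.37 ± 0.78, adjusted p = 0.0127) and miR396b-5p from 18781 ± 6175 to 14699 ± 2154 RPM (log2 change -1.29 ± 0.38, adjusted p = 0.0427). The other 6 did not pass. miR156a-5p stood at 39370 ± 21191 and 72809 ± 5819 RPM (log2 change 0.03) and miR403-3p (chromosome 2, 19415154 to 19415174), a regulator of AGO2, at 16526 ± 8903 and 42869 ± 4599 RPM (0.52). miR159b-3p (chromosome 1, 6220813 to 6220833) stood at 35528 ± 22456 and 98919 ± 22346 RPM (0.67). miR157a-5p and miR165a-3p had log2 changes of 0.17 and -2.84, and miR158a-3p had -0.73, or 0.52 with library totals. Of 227 miRNAs, 25 rose and 21 fell. TMM moved the median log2 change by -0.88, and with library totals 44 rose and 13 fell. The count was 30 without WT_total replicate 1, 27 without ago1-57_AGO1-IP replicate 2 and 24 with the 4 IP libraries alone. The call of miR396b-5p held in 1 of the 8 fits that left out a library, that without WT_AGO1-IP replicate 1, and ended with library totals, DESeq2 and exact sequences. The call of miR166a-3p ended without WT_total replicate 1 or 2 or ago1-57_AGO1-IP replicate 2, and those of miR166a-3p and miR319a ended with exact sequences and with the 4 IP libraries alone.

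For 6 of 227 miRNAs the genotype difference in IP differed from that in total RNA by the interaction test. It was larger in IP for miR158a-5p (interaction log2 2.25 ± 0.45, adjusted p = 0.0333), miR167a-3p (3.55 ± 0.57, adjusted p = 0.0317) and miR399c-5p (5.34 ± 1.1, adjusted p = 0.0333). It was lower in IP for miR390a-5p (-3.30 ± 0.60, adjusted p = 0.0317), miR5651 (-2.88 ± 0.55) and miR852 (chromosome 4, 8336302 to 8336322, -6.88 ± 1.3), which was at 1.69 ± 0.307 RPM in wild-type IP and below the floor in ago1-57 IP. miR390a-5p stood at 378 ± 8.00 RPM in wild-type total RNA and 238 ± 112 RPM in ago1-57 total RNA. The count was 0 by edgeR without WT_total replicate 1 or 2, ago1-57_total replicate 1 or ago1-57_AGO1-IP replicate 2, 16 and 18 without WT_AGO1-IP replicate 1 or 2, and 22 by DESeq2, against 37 at an unadjusted p under 0.05. Without ago1-57_AGO1-IP replicate 1 the calls of miR158a-5p, miR390a-5p and miR852 ended, and without ago1-57_total replicate 2 that of miR158a-5p. With library totals, against which TMM moved the median by -1.46, 10 were larger and 1 lower in IP, and the calls of miR390a-5p and miR5651 ended.

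The 8 most abundant miRNAs of wild-type IP, all guide strands, were higher in IP than in total RNA in both genotypes, relative to all genome-matched reads. They were chosen by their level in the same wild-type IP libraries, which favours their enrichment in the wild type. In the wild type, miR159b-3p rose by a log2 enrichment of 3.04 (adjusted p = 0.00112) and miR403-3p by 2.90 (adjusted p = 0.00166). miR156a-5p, miR157a-5p and miR158a-3p rose by 2.59 each, miR396b-5p by 2.53, miR165a-3p (chromosome 1, 78932 to 78952) by 2.35 and miR166a-3p by 2.08. In ago1-57, miR156a-5p was enriched by 5.68 ± 0.96 (adjusted p = 4.89e-08), miR403-3p by 5.48 ± 0.95, miR158a-3p (chromosome 3, 3366349 to 3366368) by 5.38, miR159b-3p by 4.96, miR165a-3p by 4.19 and miR166a-3p by 3.30. Passenger strands also rose there, miR158a-5p by 3.81, miR170-5p by 2.87 and miR162a-5p by 1.93, and guides were not tested against passengers. With TMM the first 2 of these did not pass and miR162a-5p was at -1.48. miR390a-5p was at a log2 ratio of 0.13 in the wild type, which did not pass, and fell by 1.6 in ago1-57 (adjusted p = 0.0440). Of 215 miRNAs, 121 rose and 26 fell in wild-type IP, and 155 rose and 12 fell in ago1-57 IP. These tests scale to genome-matched reads, which placed the median log2 enrichment 1.75 higher in the wild type and 3.17 higher in ago1-57 than TMM did. With TMM 21 rose and 48 fell in the wild type and 38 rose and 48 fell in the mutant, and DESeq2 gave 10 and 53, and 31 and 69. The wild-type count was 44 and 67 without WT_total replicate 1 or 2, either of which ended the calls of all 8 abundant miRNAs named. DESeq2 ended them too, and TMM all but that of miR403-3p. In ago1-57, DESeq2 and TMM ended the calls of miR157a-5p, miR165a-3p and miR166a-3p, the last with the opposite sign by DESeq2 (-0.20).

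Groups of miRNAs fixed by function, which take both strands of each family, contained members that moved in both directions. Of 56 tested members of families that regulate developmental transcription factors, 13 rose and 9 fell in IP (13 and 11 adjusted over the list alone), and 8 rose and 6 fell in total RNA (11 and 12 adjusted over the list alone). Those that rose were mostly passenger strands such as miR166a-5p and miR170-5p, and those that fell included the guides miR166a-3p and miR319a. Of 7 strands of families that control AGO and DCL genes, 2 rose in IP, the passenger strands miR162a-5p and miR168a-3p (3 adjusted over the list alone). miR168a-5p (chromosome 4, 10578652 to 10578672), the regulator of AGO1, stood at 2703 ± 1953 and 2886 ± 741 RPM in IP and did not pass. In total RNA miR162a-5p rose and the guide miR162a-3p (chromosome 5, 2634936 to 2634956), which targets DCL1, fell from 559 ± 35.8 to 174 ± 133 RPM (log2 change -1.33 ± 0.34, adjusted p = 0.0324), with 1 and 1 adjusted over the list alone. Of 7 strands of families that trigger TAS and PPR siRNAs, the guide miR390a-5p fell and the passenger miR173-3p rose in IP (1 and 1 adjusted over the list alone). In total RNA 0 passed by edgeR either way. miR161.1 (chromosome 1, 17825731 to 17825751) stood at 12290 ± 11440 and 32098 ± 12037 RPM in IP and did not pass. The 10 miRNAs sorted to other AGO proteins had 2 that rose and 2 that fell in IP (2 and 3 adjusted over the list alone), and 2 and 1 in total RNA (2 and 2 adjusted over the list alone). Those past the threshold over all miRNAs were miR166 strands and miR390a-5p. Of 52 young or species-restricted miRNAs, 2 rose and 5 fell in IP (1 and 5 adjusted over the list alone), and 1 rose and 3 fell in total RNA, the same adjusted over the list alone. Among them miR158a-5p rose and miR822-5p fell in both, and miR869.2 fell in IP from 679 ± 628 to 133 ± 17.1 RPM.

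Smaller nutrient and defence lists had few members past the threshold. Of 9 copper-responsive miRNAs, 1 fell in IP, miR408-3p, from 464 ± 305 to 127 ± 15.4 RPM (log2 change -3.16 ± 0.70, adjusted p = 0.0108), and 1 fell in total RNA, miR398b-3p. Of 6 phosphate-responsive miRNAs, miR399c-5p alone rose in IP and in total RNA, where 1 more fell adjusted over the list alone, and the guide miR399b (chromosome 1, 23345387 to 23345407) stood at 1295 and 2884 RPM in IP and did not pass. Neither of 2 sulfate-responsive miRNAs passed in either material, in edgeR's test over all miRNAs or adjusted over the list alone, and miR395b stood at 20.3 and 63.7 RPM in IP. Of 8 regulators of immune and auxin receptors, 2 rose in IP, among them miR825 (chromosome 2, 11159774 to 11159794) from 147 ± 105 to 658 ± 134 RPM (log2 change 1.39 ± 0.36, adjusted p = 0.0233), and miR863-5p alone rose in total RNA. Adjusted over the list alone, the counts of the copper list and of the receptor list were the same. Of 96 sequences that do not begin with U, which AGO1 binds less than those that do, 16 rose and 6 fell in IP (17 and 6 adjusted over the list alone) and 10 rose and 2 fell in total RNA, the same adjusted over the list alone. Of 30 sequences of 22 nt, 3 rose in IP (2 adjusted over the list alone), and 1 rose in total RNA either way. By the camera set test 0 of 11 lists passed in IP and 0 in total RNA, with lowest adjusted p of 0.522 and 0.255, 0 and 2 lists at an unadjusted p under 0.05, and adjusted p of 0.997 and 0.998 with an estimated correlation; no other set test was run.

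Passenger strands took a larger share of many miRNA duplexes in ago1-57, in AGO1 IP and in total RNA. The share is that of the passenger among reads of both strands, with the guide arm taken by family convention, a choice made after the data were seen. Duplexes named with several loci sum the reads of these loci, whose arms need not be identical. Duplexes of families without a listed convention kept the rule fixed beforehand, the strand of higher mean abundance over all libraries as guide. For miR160 (MIR160a and MIR160c; MIR160c at chromosome 5, 19009095 to 19009178) it rose from 3.89% ± 0.769 to 93.0% ± 2.89 in IP and from 32.1% ± 6.69 to 97.8% ± 1.09 in total RNA. The log2 change of its passenger to guide ratio was 8.42 ± 0.66 in IP (adjusted p = 3.55e-05) and 6.61 ± 0.63 in total RNA (adjusted p = 0.000156). For miR162 (MIR162b at chromosome 5, 7740610 to 7740696) it rose from 0.364% ± 0.0403 to 26.9% ± 7.69 in IP and from 3.74% ± 0.223 to 72.7% ± 17.5 in total RNA. For MIR396a (chromosome 2, 4142331 to 4142463) it rose from 2.60% ± 1.52 to 55.9% ± 17.6 in IP and from 17.2% ± 3.02 to 89.0% ± 6.53 in total RNA. For MIR170 and MIR171a (MIR171a at chromosome 3, 19073452 to 19073541) it rose from 29.4% ± 4.40 to 93.6% ± 1.1 in IP and from 41.5% ± 1.8 to 95.9% ± 0.720 in total RNA. For MIR169b (chromosome 5, 8527511 to 8527613), of the family that targets NF-YA factors, it rose from 2.33% ± 0.153 to 54.0% ± 3.7 in IP. Its passenger stood at 0.0681 and 0.0320 RPM in wild-type IP, below the floors of 0.204 and 0.0961 RPM, so that share is imprecise. Some shares rose from a very low base, as for MIR399c (chromosome 5, 24962497 to 24962588) from 0.0145% to 5.11% and MIR158a (chromosome 3, 3366349 to 3366411) from 0.0613% to 2.88% in IP. Reads with 3′ tails unlike the locus are left out of both strands, and no duplex test was run with them. For the guide miR158a-3p such reads were 35.7% and 39.2% in wild-type total RNA and 71.5% and 73.5% in ago1-57 total RNA. By the interaction test the change was larger in IP than in total RNA for MIR399c (log2 6.16), MIR390a and MIR390b (4.38, adjusted p = 0.00140), MIR168a and MIR168b (3.09) and MIR167a (2.64). The interaction calls of the last 2 ended without WT_total replicate 1 or 2 or either ago1-57_AGO1-IP replicate. In IP the share of MIR390a (chromosome 2, 16061971 to 16062043) rose from 0.232% ± 0.0414 to 4.12% ± 0.335, that of MIR168a (chromosome 4, 10578652 to 10578757) from 2.72% ± 0.22 to 12.8% ± 2.32, and that of MIR167a (chromosome 3, 8108090 to 8108192) from 2.16% ± 0.258 to 23.7% ± 2.2.

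Of 55 duplexes tested with the guide arm by family, 20 rose and 2 fell in IP, and 17 rose and 3 fell in total RNA. Under the rule fixed beforehand, which takes as guide the strand of higher mean abundance over all libraries, 16 rose and 6 fell in IP, and 13 rose and 7 fell in total RNA. With the guide from the wild-type libraries, also chosen after the data were seen, 22 rose and 0 fell in IP by edgeR, and 18 rose and 2 fell in total RNA. That IP test had 24 duplexes at an unadjusted p under 0.05 and no other tool was run. This rule makes the lesser strand of the wild type the passenger and so favours rises in the mutant by construction. The difference between these splits lies in duplexes such as miR160, MIR169b (in IP), MIR170 and MIR171a, and MIR171b and MIR171c, whose conventional passenger was the more abundant strand over all libraries. The sign of their ratio is opposite under that rule, with -8.42 for miR160 in IP. The IP count was 14 with the 4 IP libraries alone, and the total RNA count was 8 and 7 without WT_total replicate 1 or 2 and 11 without ago1-57_total replicate 2. The call of MIR169b ended with the 4 IP libraries alone, and MIR3440b, which fell in both, had IP groups with no read of a strand, so no fold is given there.

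**Figure D2:**
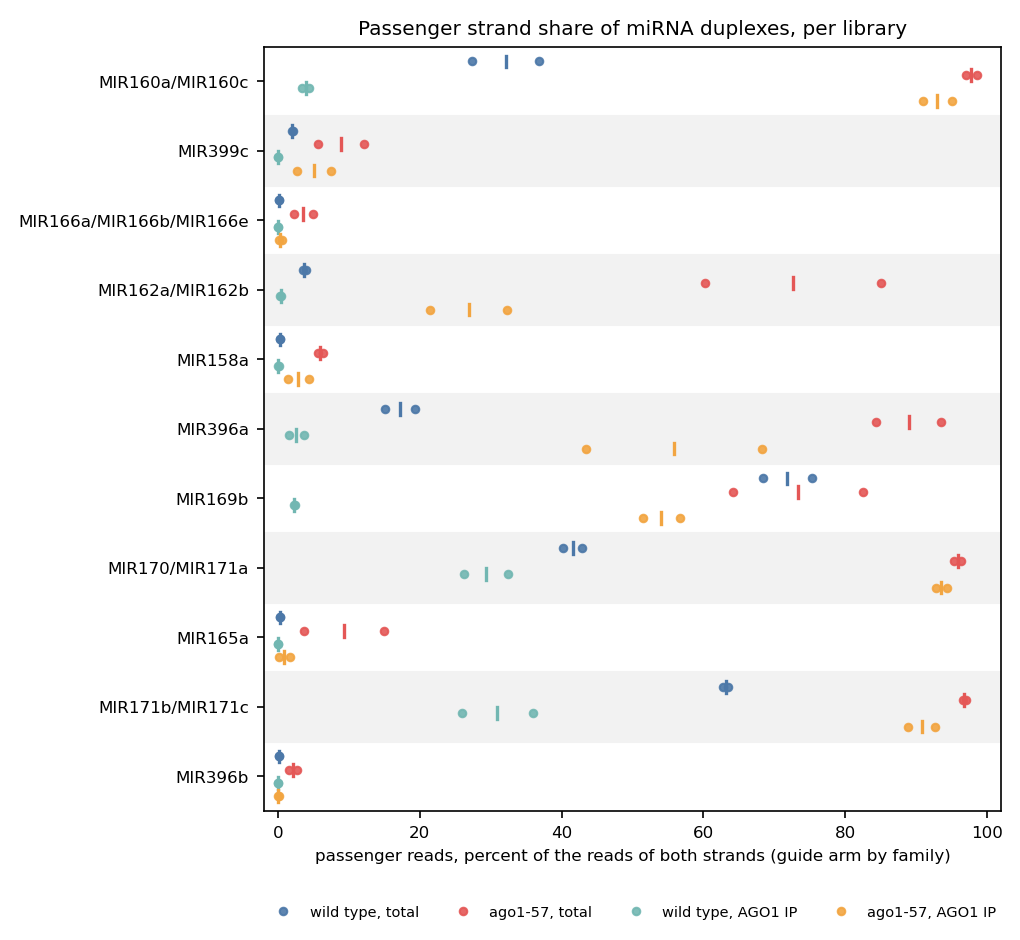
Passenger share in percent of both strands for 11 miRNA duplexes, with the guide arm by family, in the 4 groups; dots are libraries and vertical ticks the mean of both libraries. For miR160 the share in AGO1 IP is 3.89% ± 0.769 in the wild type and 93.0% ± 2.89 in ago1-57.

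The change in passenger share was compared with how well the strands of a duplex pair. Across 55 miRNA duplexes the log2 change in IP and the number of unpaired guide nucleotides gave Spearman's rho of -0.12 (permutation p = 0.391) and Pearson's r of -0.05 (permutation p = 0.704). Duplexes are not independent replicates. Without the 2 duplexes of most extreme pairing, rho was -0.12 and r -0.07. With the unpaired fraction of guide positions 2 to 13, rho was 0.15 (permutation p = 0.275), the opposite sign. These values use the guide rule fixed beforehand, and with the guide arm by family rho was -0.17 (permutation p = 0.222) and 0.012 (permutation p = 0.930). Of 5 pairing measures examined with the guide arm by family, 0 passed in the permutation tests after adjustment and 1 before it, with no other test run. That was the predicted pairing energy, with rho of -0.31 (permutation p = 0.0234, adjusted p = 0.117).

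At siRNA loci, whose duplexes pair fully, the strand without a 5′ U also took a larger share in ago1-57. This share was summed by locus over 21-nt duplexes of which a single strand begins with U, a summary chosen after the data were seen. At TAS2 (AT2G39681, chromosome 2, 16539384 to 16540417), a source of trans-acting siRNAs cut by miR173, it rose from 0.187% ± 0.165 to 10.2% ± 4.9 in IP and from 0.956% ± 0.0817 to 31.5% ± 11.4 in total RNA. The log2 change of the strand ratio in IP was 6.17 ± 1.05 (adjusted p = 5.39e-06). At TAS1A (AT2G27400, chromosome 2, 11721539 to 11722468) it rose from 4.59% ± 3.2 to 29.3% ± 1.66 in IP and from 23.1% ± 3.38 to 76.0% ± 0.429 in total RNA. At TAS1B (AT1G50055, chromosome 1, 18549204 to 18550042) it rose from 2.07% ± 0.387 to 12.4% ± 2.16 in IP and from 6.55% ± 0.0132 to 53.5% ± 6.95 in total RNA. At AT5G38850 (chromosome 5, 15555156 to 15558882), a gene of the TIR-NBS-LRR immune receptor class, it rose from 2.01% to 15.5% in IP, and over 258 intergenic duplexes from 8.05% to 34.4%. At TAS1C (AT2G39675, chromosome 2, 16537288 to 16538277) it was 1.76% and 3.02% in IP and did not pass (log2 change 0.94, adjusted p = 0.472). Of 11 loci or classes with at least 5 such duplexes, 9 had a larger share in IP and 6 in total RNA. With 1 library left out, 7 to 10 had a larger share in IP and 4 to 8 in total RNA. Single duplexes showed exchanges of the more abundant strand. In a TAS1A duplex at 11722007 to 11722029 the strand beginning with U made up 94.4% and 94.8% in the wild-type IP libraries and 11.8% and 5.93% in the ago1-57 ones. In a TAS2 duplex at 16539810 to 16539832 it made up 78.9% and 89.6% in wild-type IP and 0.817% and 0.332% in ago1-57 IP. In another at 16539746 to 16539768 it made up 97.2% and 99.4%, then 34.1% and 17.7%. In total RNA, the strand without a 5′ U of a TAS3 duplex (chromosome 3, 5862331 to 5862353) rose from 1.82% and 0.654% to 92.4% and 96.4%.

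Of 1268 siRNA duplexes tested one by one with the more abundant strand as guide, the passenger to guide ratio rose in 19 and fell in 15 in IP, and rose in 10 and fell in 5 in total RNA. With the strand beginning with U as guide, a choice made after the data were seen, 23 of 650 rose and 1 fell in IP, and 14 rose and 0 fell in total RNA. There 56 were at an unadjusted p under 0.05 in either direction by edgeR, and no other tool was run. The IP count was 10 with the 4 IP libraries alone, 20 without WT_total replicate 1 or 2 and 19 without ago1-57_AGO1-IP replicate 2. The total RNA count was 25 over duplexes of at least 200 reads, 45 with the 4 libraries alone, 5 and 3 without WT_total replicate 1 or 2, 9 and 8 without ago1-57_total replicate 1 or 2, and 30 and 32 without WT_AGO1-IP replicate 1 or 2.

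**Figure D3:**
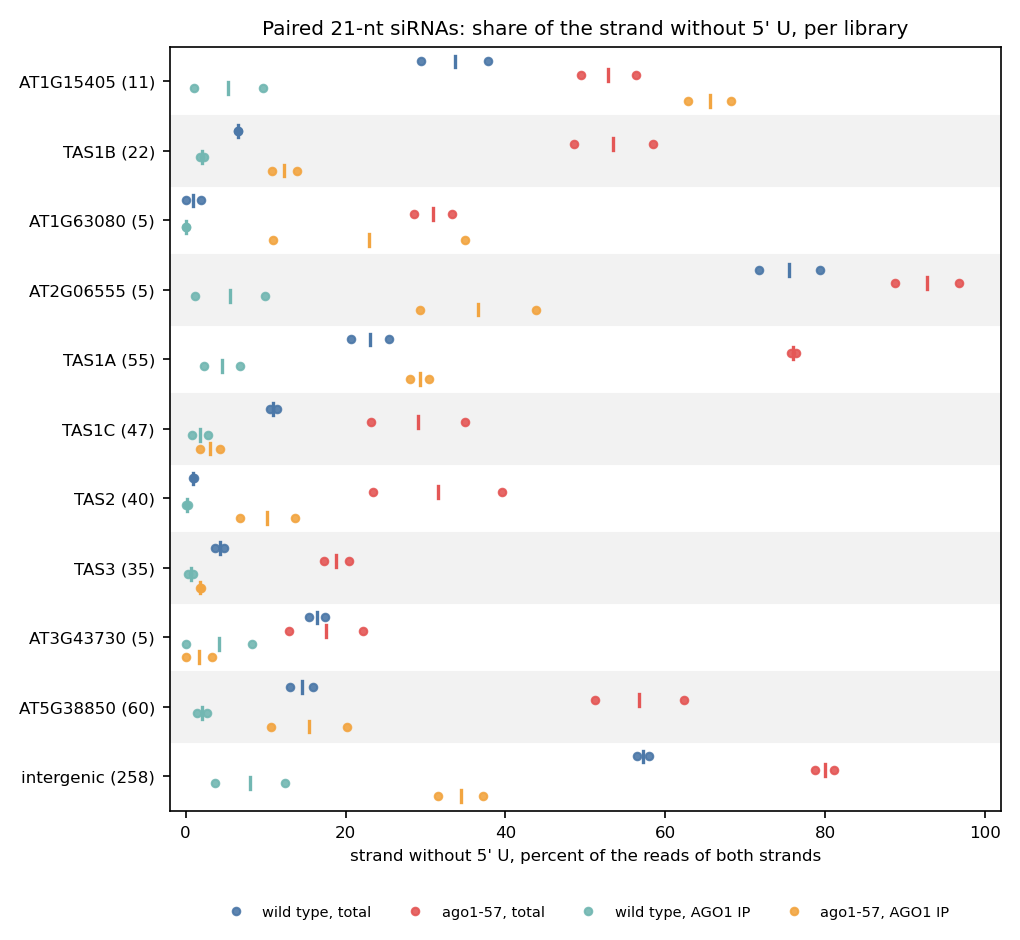
Share in percent of the strand without a 5′ U, summed over 21-nt siRNA duplexes, at 11 loci or classes with the number of duplexes in parentheses, in the 4 groups; dots are libraries and vertical ticks the mean of both libraries. At TAS1A the share in total RNA is 23.1% ± 3.38 in the wild type and 76.0% ± 0.429 in ago1-57.

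Secondary siRNAs of 21 to 22 nt from pentatricopeptide repeat (PPR) genes, which are targets of miR161, miR400 and TAS-derived siRNAs, were lower in ago1-57. Of 13 PPR genes tested from a fixed list of 16, 11 fell in total RNA (13 adjusted over the list alone) and 11 fell in IP (11 adjusted over the list alone), with median log2 changes of -2.74 and -3.28. The set test gave adjusted p = 5.47e-126 in total RNA and 1.06e-42 in IP, and adjusted p = 0.00131 and 0.0119 with an estimated correlation. RPF2 (AT1G62670, chromosome 1, 23204256 to 23206822), a mitochondrial RNA processing factor, fell from 2.83 ± 0.781 to 0.129 ± 0.0775 RPM in total RNA and from 11.4 ± 5.77 to 0.781 ± 0.202 RPM in IP (log2 change -4.19 ± 0.42, adjusted p = 0.000181). AT1G62914 (chromosome 1, 23301315 to 23303162) fell from 20.6 ± 3.88 to 1.85 ± 0.359 RPM in total RNA and from 83.9 ± 41.1 to 10.8 ± 1.65 RPM in IP. AT1G63080 (chromosome 1, 23387574 to 23390838) fell from 43.6 ± 6.89 to 8.38 ± 0.203 RPM in total RNA and from 193 ± 87.5 to 78.3 ± 15.1 RPM in IP, where the call ended with library totals (log2 change -1.30 ± 0.52, against -1.65 ± 0.20). PPR genes outside that list, AT1G12775 (chromosome 1, 4353842 to 4355929) and AT1G12620 (chromosome 1, 4294552 to 4297178), were among the 10 largest changes in total RNA. The former fell from 12.4 ± 2.56 to 0.418 ± 0.0721 RPM (log2 change -4.87 ± 0.37, adjusted p = 2.65e-05). MEE40 (AT3G53700, chromosome 3, 19900240 to 19903173), a gene of the PPR family outside the list that was chosen after its values were seen, moved the other way. It rose in IP from 0.202 ± 0.195 to 3.34 ± 1.73 RPM (log2 change 3.99, adjusted p = 0.0210) and did not pass in total RNA (adjusted p = 0.138). These genes are close paralogs, so counts of reads with 1 genome match can miss part of their reads.

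**Figure D4:**
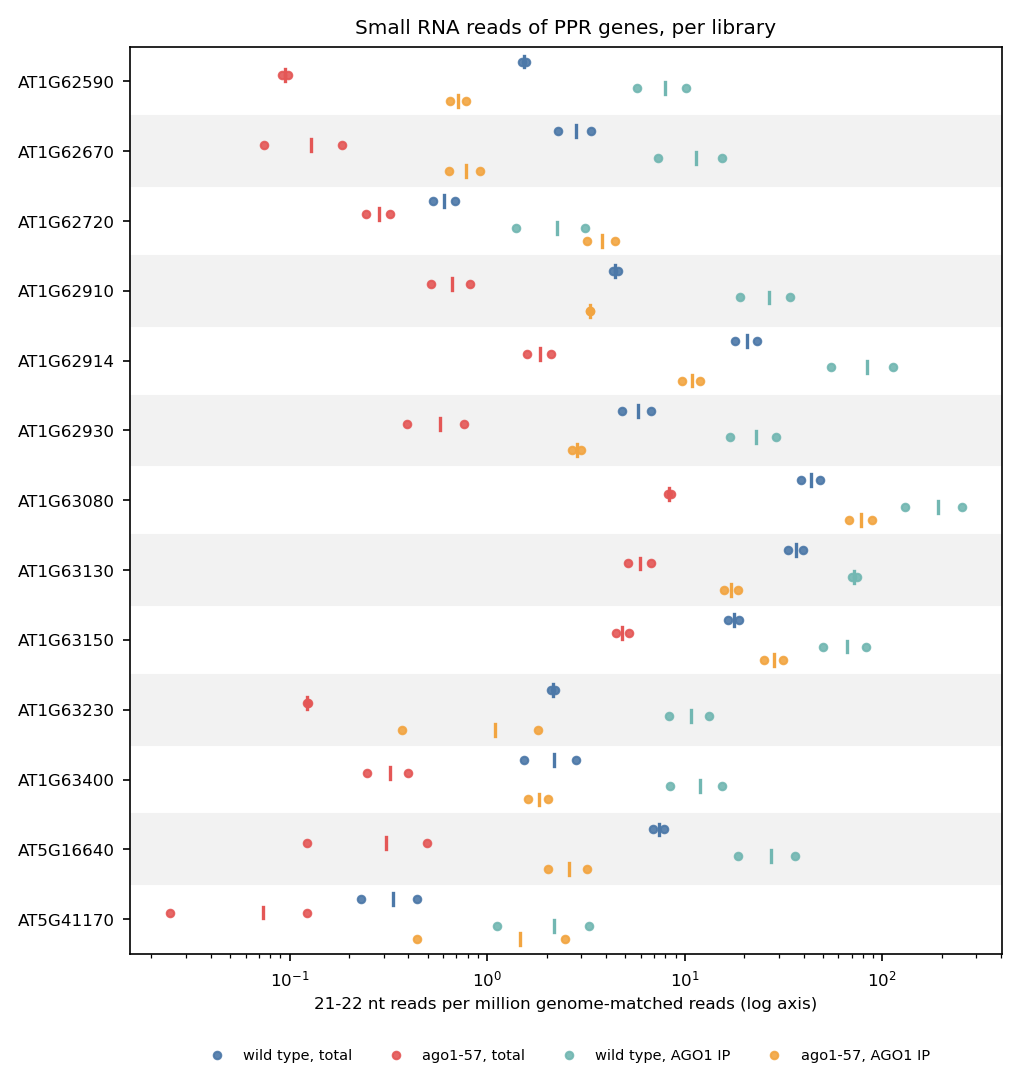
Reads of 21 to 22 nt from 13 PPR genes in RPM on a log axis in the 4 groups; dots are libraries and vertical ticks the mean of both libraries. RPF2 stands at 2.83 ± 0.781 RPM in wild-type and 0.129 ± 0.0775 RPM in ago1-57 total RNA.

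Among 8 TAS loci, TAS1B alone fell over all loci tested, from 445 ± 32.2 to 129 ± 12.3 RPM in total RNA (log2 change -1.78 ± 0.27, adjusted p = 0.00705) and from 1867 ± 235 to 691 ± 132 RPM in IP (log2 change -1.94 ± 0.27, adjusted p = 0.00243). TAS2 stood at 2283 and 1304 RPM in total RNA and at 14610 and 17732 RPM in IP. TAS1C stood at 4069 and 2113 RPM and at 21003 and 27295 RPM, and TAS3 (AT3G17185, chromosome 3, 5861491 to 5862437) at 620 and 523 RPM and at 3837 and 5727 RPM. None of these 3 passed. Adjusted over the list alone, 4 TAS loci fell in total RNA and 2 in IP. The set test gave adjusted p = 1.56e-07 in total RNA (adjusted p = 0.0891 with an estimated correlation) and 0.428 in IP (0.733), where its direction was down and the median log2 change 0.01. Small RNAs of AGO1 (AT1G48410, chromosome 1, 17885633 to 17892632) fell from 12.9 ± 0.162 to 3.68 ± 1.09 RPM in total RNA and from 43.3 ± 11.2 to 14.8 ± 0.906 RPM in IP (log2 change -1.96 ± 0.28, adjusted p = 0.00328). Those of DCL1 (AT1G01040, chromosome 1, 23121 to 31227) fell in IP from 11.9 ± 3.34 to 6.29 ± 0.772 RPM, and those of AGO2 (AT1G31280, chromosome 1, 11181504 to 11185396) stood at 14.4 and 35.9 RPM in IP and did not pass. In the list of these 3 genes 1 fell in total RNA and 2 in IP (1 and 2 adjusted over the list alone, with 1 that rose in IP). The set test gave adjusted p = 1.09e-06 and 0.0268, and adjusted p = 0.0493 and 0.287 with an estimated correlation. Of 3 auxin receptor genes, AFB2 (AT3G26810, chromosome 3, 9867652 to 9870782) fell in IP from 14.3 ± 3.35 to 6.62 ± 2.91 RPM while 0 passed in total RNA by edgeR. Adjusted over the list alone, 1 fell in total RNA and 2 in IP. The set test gave adjusted p = 0.0075 and 0.0268, and adjusted p = 0.163 and 0.287 with an estimated correlation. With library totals the calls of TAS1B, AGO1, DCL1 and AFB2 ended, as the estimated spread grew and, in IP, the changes shrank. In total RNA TAS1B was at -1.79 ± 0.57 and AGO1 at -1.81 ± 0.51, against -1.78 ± 0.27 and -1.82 ± 0.29 with TMM. In IP TAS1B was at -1.43 ± 0.56, AGO1 at -1.55 ± 0.50, DCL1 at -0.92 ± 0.51 and AFB2 at -1.12 ± 0.51, where DCL1 and AFB2 had been at -1.34 ± 0.29 and -1.61 ± 0.31. Their IP calls ended also with the 4 IP libraries alone. Weighting reads with several genome matches ended the total RNA call of TAS1B (log2 change -1.26 ± 0.26) and the IP call of AFB2 (-1.19 ± 0.24, adjusted p = 0.0514). The IP call of DCL1 ended also without WT_total replicate 1 or 2, WT_AGO1-IP replicate 2 or either ago1-57_AGO1-IP replicate, and that of AFB2 without WT_AGO1-IP replicate 2 or ago1-57_AGO1-IP replicate 1.

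Over all 7391 loci tested, 7 rose and 24 fell in total RNA and 16 rose and 73 fell in IP. Many of the largest changes in IP concerned sparsely read genes: 12 of the 73 had no read in either mutant library and 2 of the 16 had none in either wild-type library. CKX4 (AT4G29740, chromosome 4, 14566183 to 14569380), a cytokinin oxidase, was at 3.04 RPM in wild-type IP and at least 14.3-fold lower in ago1-57 against a floor of 3 reads per library. FPS1 (AT5G47770, chromosome 5, 19345110 to 19347677), a farnesyl diphosphate synthase, was at 1.67 RPM and at least 7.88-fold lower, a call that ended with weighted reads. COL5 (AT5G57660, chromosome 5, 23355337 to 23356989), a CONSTANS-like protein, was at least 6.68-fold lower and AGL23 (AT1G65360, chromosome 1, 24281337 to 24282233), a MADS-box gene, at least 5.35-fold lower. The long noncoding RNA AT3G07775 (chromosome 3, 17520412 to 17521027) was at 2.08 RPM in ago1-57 IP and at least 13.9-fold higher, a call that ended without WT_AGO1-IP replicate 1. AT1G71850 (chromosome 1, 27024731 to 27026363), of a ubiquitin hydrolase family, was at least 14.2-fold higher, a call that ended without WT_total replicate 2 or any 1 of the 4 IP libraries. By the interaction test 0 loci differed between IP and total RNA with edgeR, against 451 at an unadjusted p under 0.05, 3 by DESeq2, 24 without the filter on low counts and 4 without WT_AGO1-IP replicate 1. With library totals 2 rose and 19 fell in total RNA and 27 rose and 38 fell in IP, where TMM had moved the median by -0.35. The calls of the 6 genes above ended with the 4 IP libraries alone. The IP count was 156 by DESeq2, 190 without the filter, 19 with the 4 IP libraries alone and 139 without WT_AGO1-IP replicate 2. In that last fit 71 rose and 68 fell, so the excess of falls in IP depended on that library. The total RNA count was 65 with 4 libraries and 20 without WT_total replicate 2.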

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

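The interaction test of miRNAs was planned, while the interaction test of duplexes and all tests of explanations in this part were chosen after the results were seen.

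The difference between ago1-57 and the wild type differed between AGO1 IP and total RNA, by a test of that difference, for 6 miRNAs. The interaction was 2.25 for miR158a-5p, 3.55 for miR167a-3p and 5.34 for miR399c-5p, all larger in IP. It was -3.30 for miR390a-5p, -2.88 for miR5651 and -6.88 for miR852, all lower in IP. None of these 6 passed without WT_total replicate 1 or 2, ago1-57_total replicate 1 or ago1-57_AGO1-IP replicate 2, where edgeR called 0 miRNAs, against 37 at an unadjusted p under 0.05 and 22 by DESeq2 with all libraries. With the guide arm by family, the log2 interaction of the passenger to guide ratio was 2.64 for MIR167a, 3.09 for MIR168a and MIR168b, 4.38 for MIR390a and MIR390b, and 6.16 for MIR399c.

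Relative to guides, passenger strands were higher in the AGO1 IP of ago1-57 in 20 of 55 miRNA duplexes and lower in 2 (guide by family). Under the rule fixed beforehand 16 rose and 6 fell. Carry-over of RNA not bound by AGO1, scaled by ribosomal RNA (2.28% and 3.75% of genome-matched reads in mutant IP, 47.5% and 51.9% in mutant total RNA), is argued against, since the passengers stood at a median of 48.1 and 61.6 times the level it allows. A change of strand shares limited to duplexes with unpaired bases is argued against by fully paired siRNA duplexes. At 8 of 10 loci of these, the strand without a 5′ U had a larger share in IP. In total RNA 5 of these loci had a larger share too, so they do not place the change in AGO1. That share goes by first nucleotide, so it does not show that the passenger share of siRNA duplexes rose. With the more abundant strand as guide, 19 of 1268 siRNA duplexes rose and 15 fell in IP. An IP that follows total RNA is argued against for the passenger to guide ratio of the 4 duplexes with an interaction. For MIR390a and MIR390b the ratio also reflects the guide, which fell from 415 and 409 RPM in wild-type IP to 65.8 and 91.5 RPM in ago1-57 IP. Their passenger stood at 1.09 and 0.832 RPM, then 2.99 and 3.69 RPM. The MIR399c passenger stood at 0.0681 and 0.288 RPM in wild-type IP, the first below its floor of 0.204 RPM. The interaction of MIR167a and that of MIR168a and MIR168b did not pass without WT_total replicate 1 or 2 or either ago1-57_AGO1-IP replicate, and the latter also without WT_AGO1-IP replicate 2. Of the other 16 duplexes that rose, 12 rose in total RNA too, and for these a change made in AGO1 cannot be told apart from one already present in total RNA. The rest passed neither in total RNA nor by the interaction, so the question stayed open. Among them are MIR169b (log2 5.49 in IP, 0.18 in total RNA) and MIR173 (2.75 and -0.51). A difference in how the mutant protein releases the passenger may contribute, but the genotype is the one difference the labels name and this explanation was not tested.

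Summed miRNAs were lower in total RNA of ago1-57, by a log2 change of -2.06. Dilution that would lower 24-nt reads as well is argued against, since 24-nt reads beginning with A had a log2 change of 0.12 (SE 0.46). A rise of all other classes together cannot be told apart from a fall of miRNAs, because levels are shares of each library. A change of miR165 and miR166 alone is argued against, since the lowest wild-type sum of the other miRNAs was 1.58 times the highest mutant sum. In 32 duplexes the median change of guides minus that of passengers was -1.32 (medians -1.23 and 0.09), with the guide below the passenger in 27. That difference restates the passenger to guide ratio of total RNA (correlation 0.991), so it is no separate test, and loss of the strands that wild-type AGO1 holds cannot be told apart from other causes. Lower transcription or processing of miRNA precursors remained open, since precursors were not measured.

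Reads of 21 to 22 nt from PPR genes were lower in ago1-57. Missing shared reads are argued against as the cause, since 13 of 15 PPR genes fell in IP when reads with several genome matches were weighted. Weighting splits such reads over paralogs, so the 13 are not separate results. In counts of reads with 1 genome match, which paralogs cannot share, 11 of 13 fell in IP. Less trigger miRNA in AGO1 remained open and cannot be told apart, because the lowest log2 change of miR161.1, miR161.2 and miR400 in IP was -0.49, while its lower bound of -1.77 lies below -1.64, a level at 0.5 of the median PPR change. Weaker triggering by mutant AGO1 may contribute and was not tested.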

How the results depend on the processing

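The wild-type, 5′ U and family guide rules, the pairing measures with the guide by family, the counts with tailed reads and all settings of the duplex interaction and of siRNA loci were added after the data were seen; the other settings were planned. Depth and 2 libraries per group limit the calls: the simulated miRNA test in total RNA found 50% of changes of log2 2, and the test of siRNA duplexes in IP found 25% of changes of log2 8. Counts per comparison that moved by less than 1.5 times are not listed. The cause of a moved or reversed value below was not tested, except that a changed guide rule exchanges the strands of a ratio by construction. Fits on 4 libraries have fewer samples and their own spread, and fewer samples alone would not raise the counts in total RNA. Replicates correlated (Pearson, log2 RPM of miRNAs) at 0.997 in wild-type total RNA, 0.980 in ago1-57 total RNA, 0.956 in wild-type IP and 0.981 in ago1-57 IP. A spread shared by unlike groups can make p-values too small in IP and too large in total RNA. The set tests of the 11 miRNA lists gave 0 calls in all settings run, each a camera test on the edgeR fit, with 0 and 2 unadjusted in the main setting for IP and total RNA and no other tool.

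With DESeq2 the miRNA count was 45 in total RNA against 28, 63 for IP over total RNA in the wild type against 147 and 100 in ago1-57 against 167, and 22 for the interaction against 6. It was 156 for loci in IP against 89 and 3 for the locus interaction against 0 by edgeR (451 unadjusted), and 13 and 15 size classes in total RNA and IP against 1 and 6. DESeq2 reversed the sign of miR166a-3p for IP over total RNA in ago1-57 (-0.20), of TAS1A (AT2G27400, 0.057) and TAS2 (AT2G39681, 0.022) in IP and of the 24-nt class beginning with A in total RNA (-0.35). TMM in place of library totals gave 69 miRNAs for IP over total RNA in the wild type and 86 in ago1-57. Library total scaling gave 11 miRNAs for the interaction and reversed miR157a-5p (-0.37) and miR159b-3p (-0.44) in total RNA, and miR158a-3p (0.52), TAS1A (0.40) and TAS2 (0.28) in IP. Without the filter on low counts the interaction had 19 miRNAs and 24 loci, loci in IP numbered 190, and TAS1C (AT2G39675) was at -0.11 in IP. Exact mature sequences gave 11 miRNAs for the interaction and miR156a-5p at -0.011 in IP, tailed reads gave miR158a-3p at 0.087 in IP, weighted reads gave TAS1A at 0.031 in IP, and genome-matched reads gave 2 size classes in total RNA.

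With only the 4 libraries compared, the count was 83 miRNAs in total RNA and 24 in IP against 46, 65 loci in total RNA against 31 and 19 in IP, 14 miRNA duplexes in IP against 22, and 10 siRNA duplexes in IP against 34 and 45 in total RNA against 15. In IP it put miR156a-5p at -0.0089, TAS1A at 0.042 and TAS2 at 0.0070. At least 200 reads per duplex gave 25 siRNA duplexes in total RNA. Unpaired positions 2 to 13 gave rho of 0.15 against -0.12 with the planned guide, and 0.012 against -0.17 with the guide by family. The guide by family and that of the wild-type libraries turned the ratio of miR160 (MIR160a/MIR160c) to 8.42 in IP and 6.61 in total RNA, of MIR170/MIR171a to 5.15 and 5.04, of MIR169b to 5.49 in IP and of MIR171b/MIR171c to 4.14 in total RNA. The wild-type guide turned MIR3440b to 17.17 in IP, a fitted value with groups at 0, and 6.41 in total RNA. The guide of the total RNA libraries turned MIR396a to -5.72 in IP and -5.42 in total RNA, and the TAS3 duplex d000737 to -14.34 and -10.33 and the TAS1A duplex d000462 to -11.76 and -8.13, of which the IP values are fitted with no wild-type IP read of a strand. The 5′ U guide turned duplexes d000526, d000039, d000166, d000662, d000481 and d000606 in IP to 18.58, 17.39, 15.65, 12.98, 12.38 and 10.46, fitted values with libraries that lack reads of a strand and so no folds, and d000596, d000574 and d000449 in total RNA to 7.78, 7.57 and 6.73.

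With each library left out in turn, edgeR counts ranged from 0 to 47 miRNAs in total RNA, 27 to 55 in IP, 44 to 163 for IP over total RNA in the wild type and 0 to 18 for the interaction. They ranged from 20 to 35 loci in total RNA, 71 to 139 in IP and 0 to 4 for the interaction, from 7 to 20 miRNA duplexes in total RNA, 19 to 40 siRNA duplexes in IP and 3 to 32 in total RNA, and from 0 to 2 and 1 to 15 size classes in total RNA and IP. With the guide by family 2 to 5 miRNA duplexes passed the interaction, and 7 to 10 siRNA loci or classes rose in IP and 4 to 8 in total RNA. The siRNA strand ratio of AT3G43730 ranged from -6.10 to 4.91 in IP, fitted with libraries that lack reads of a strand, and from -0.44 to 0.49 in total RNA. In total RNA miR157a-5p ranged from -0.13 to 0.45, miR159b-3p from -0.35 to 0.48, TAS1A from -0.011 to 0.16, AT3G25795 from -1.02 to 1.35, TIR1 (AT3G62980) from -1.35 to 0.11 and AFB3 (AT1G12820) from -0.65 to 0.0095. In IP miR157a-5p ranged from -0.23 to 0.98, miR158a-3p from -1.92 to 0.76, miR156a-5p from -0.062 to 0.23, TAS1A from -0.34 to 0.34, TAS1C from -0.50 to 0.37, TAS2 from -0.32 to 0.16, AT5G57735 from -0.25 to 0.75 and TIR1 from -0.35 to 1.08. The 22-nt and 20-nt classes beginning with U ranged from -0.33 to 0.94 and from -0.15 to 0.93 in IP.

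Replicate numbers are shared by the groups, but nothing says that they pair libraries, and the deviations of equal numbers correlated between -0.24 and 0.36. With the number as a replicate block edgeR called 25 miRNAs in total RNA, 43 in IP, 140 and 164 for IP over total RNA, and 7 for the interaction. The replicate block gave 32 loci in total RNA, 100 in IP and 0 for the interaction, 21 and 16 miRNA duplexes, 26 and 15 siRNA duplexes, 7 and 1 size classes in IP and total RNA, and TAS1C at -0.037 in IP.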

Other observations

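All tests of the tail hypothesis in this part, and the genes named here, were chosen after the results were seen.

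Other loci outside the named groups also moved. Small RNAs of 21 to 22 nt from ARF4 (AT5G60450, chromosome 5, 24308255 to 24312784), an auxin response factor targeted by TAS3 siRNAs, fell from 7.87 ± 0.205 to 2.12 ± 1.13 RPM in total RNA and from 76.1 ± 56.9 to 9.72 ± 3.89 RPM in IP (log2 change -3.20 ± 0.31, adjusted p = 0.000151). Those of BIM1 (AT5G08130, chromosome 5, 2606002 to 2610250), a brassinosteroid signalling factor, fell from 6.32 ± 3.77 to 0.593 ± 0.0754 RPM in IP (adjusted p = 0.00144). Those of HAM1 (AT2G45160, chromosome 2, 18617862 to 18620451), a scarecrow-like target of miR171, fell from 8.18 ± 3.83 to 3.36 ± 0.73 RPM in IP (adjusted p = 0.0184), a call that ended with library totals (log2 change -1.28 ± 0.55 against -1.63 ± 0.31, adjusted p = 0.279). The PPR pseudogene AT1G62860 (chromosome 1, 23274487 to 23277075) fell from 9.27 ± 0.726 to 1.18 ± 0.0724 RPM in total RNA and from 42.4 ± 26.1 to 8.16 ± 0.0488 RPM in IP (log2 change -2.62), a call that ended with weighted reads (log2 change -1.24, adjusted p = 0.0634). In contrast, 2 transcribed regions of no known function rose in both materials. AT3G00210 (chromosome 3, 1960503 to 1962764) rose from 2.33 ± 0.861 to 35.5 ± 12.5 RPM in total RNA and from 2.80 ± 0.378 to 78.1 ± 6.46 RPM in IP (log2 change 4.34 ± 0.39, adjusted p = 9.47e-05). AT1G09805 (chromosome 1, 24720922 to 24721298) rose from 50.1 ± 2.97 to 162 ± 17.6 RPM in total RNA and from 241 to 874 RPM in IP. Both calls of AT1G09805 ended with library totals (adjusted p = 0.829 in total RNA and 0.105 in IP) because the estimated spread grew, with log2 changes of 1.69 ± 0.55 and 1.86 ± 0.55 against 1.69 ± 0.20 and 1.51 ± 0.20.

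Reads without a genome match made up 14.6% and 8.48% of the wild-type IP libraries and 22.0% and 20.7% of the ago1-57 ones. A candidate explanation is nucleotides added to the 3′ end of miRNAs. Reads counted as tailed began with at least the first 16 nt of a mature miRNA and ended in up to 8 nucleotides unlike its locus. A mismatch inside the mature sequence thus counts as a tail, and these reads were not checked for a genome match elsewhere. Tailed reads made up 8.24% and 4.04% of all reads in wild-type IP and 16.3% and 13.5% in ago1-57 IP. Their rise of 8.78 percentage points equals 89.8% of the rise of 9.78 points in reads without a match. This fits that hypothesis as far as these reads lack a match and end in added nucleotides. The nucleotides unlike the locus were mostly U. Part of the rise may follow from which miRNAs are abundant: with the mean wild-type IP tail share of each of the 30 miRNAs, the mutant IP libraries would have 20.2% and 16.4% of miRNA reads tailed, against 24.8% and 24.7% observed among the same miRNAs. In total RNA, 6.20% and 5.73% of miRNA reads were tailed in the wild type and 17.7% and 19.3% in ago1-57. By edgeR 1 of 30 miRNAs had a larger tailed share in mutant IP, miR396a-5p (log2 change of the tailed to untailed ratio 1.6 ± 0.28, adjusted p = 0.0296). Its tailed reads made up 57.4% and 56.2% in mutant IP, but those with only U in the tail 2.72% and 2.38%. In 13 cases mature sequences shared their first 16 nt, and reads that fitted several equally were given to 1 of them. Reads of a paralog counted as tailed were therefore not told apart from tails of miR396a-5p. In total RNA 0 of 30 passed, with 12 at an unadjusted p under 0.05, and the interaction gave 0, with 1 unadjusted, and no other tool was run. These tails were not told apart from sequencing errors at read ends.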
